A study of Homo sapiens with 10 samples.

How the data were processed

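Human primary fibroblasts were kept in 0.1% serum for 48 h and were then given 10% serum for 0, 2, 4, 6 or 8 h. Per the labels, each of the 5 times has 2 independent biological replicates, and whether these share a donor is not stated there. The RNA of each of the 10 samples was hybridised to 1 Affymetrix expression array, which carries 54675 probe sets. The number of arrays, 2 at each time, limits the precision of every value.

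The deposited values were signal intensity of each probe set on a linear scale. The authors computed them with MAS5 in GCOS, per the submitters' processing notes, which give no versions. The authors scaled each array to a common mean signal. This was checked on the values: without the top and bottom 2% of probe sets, the mean signal was 150 on all 10 arrays. No genome build applies to array probe sets, and no arrays were pooled. Detection calls were not used here.

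Of the 54675 probe sets, 41097 carried exactly 1 gene symbol, 1801 carried several and 11777 carried none. Signals were analysed as log2(signal + 16), with no further normalization between arrays. Probe sets above the median of the mean log2 values over the 10 arrays were kept, which corresponds to a signal of 36.92 or more on that scale. Each gene was represented by its probe set with the highest mean among those with 1 symbol, which left 12998 of 19732 genes for the tests. The 62 control probe sets were used for array quality only. Because 16 was added before the logarithm, fold changes understate the change of dim genes. For named genes whose dimmer group mean lay under 36.92, the change was computed again with signals under that level raised to it, and it is given as a bound. These bounds were chosen after the values were seen, and they do not allow for the spread between the arrays of a time.

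All 10 arrays entered 1 linear model of the 5 group means in limma 3.58.1 under R 4.3.3, with moderated variances and a trend of the variance with brightness (5 residual and 7.66 prior degrees of freedom). Each of 2, 4, 6 and 8 h was compared with 0 h, and 2 h with 4 h, 4 h with 6 h, 6 h with 8 h and 2 h with 8 h were compared as intervals. A gene counted as risen or fallen when its limma p-value, adjusted by Benjamini-Hochberg within the comparison, was under 0.05. All tests were two-sided. An F test over the 5 times used the same model. A single gene with 2 arrays against 2 cannot go below p = 0.333 in an exact permutation test, so every call rests on the variance that limma shares across genes and times. SE values are those of the log2 change.

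A set of 31 gene lists for serum-stimulated fibroblasts and 7 lists of cell type markers was fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes. The p-values of the 31 lists were adjusted together over the 4 comparisons with 0 h, and separately over the 4 interval comparisons. The marker lists formed families of their own. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were the alternatives. For each list, the number of members past the threshold is given over all genes tested and when adjusted over the list alone.

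Genes were named by rule. For each comparison with 0 h, these were the 10 largest rises and the 10 largest falls among called genes whose 4 array-to-array differences all had one sign. Probe sets marked by the manufacturer as likely to cross-hybridise, unnamed loci, antisense and microRNA host genes and sex-linked markers were left out of that ranking. The interval comparisons used the 5 largest each way. For each list, up to 4 called members with the largest change were named, or up to 2 members where none was called. List members were not screened for cross-hybridisation. The values of NR4A1, CXCL8, IDI1 and HES4, among others, come from probe sets marked in that way. A fixed set, FOS, EGR1, JUNB, MYC, CCND1, SRF, CDKN1B, IL6, CCN2, CCNE1, CCNE2 and E2F1, was named throughout. Some genes of the lists and of the fixed set are not reported here.

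Overlaps of calls between times were set against the number expected from independent draws, which does not allow for the 0 h arrays that these comparisons share. They were also set against 100 simulated data sets in which no time had an effect and all comparisons used the same simulated 0 h arrays. With 2 arrays at 0 h, no split left 2 of them to each comparison.

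The alternatives changed 1 choice at a time. They were quantile normalization, scaling of each array to a common median, pseudocounts of 1 and 64, no filter on dim probe sets, the upper 25% of probe sets, no variance trend, a robust variance prior, the mean of all probe sets of a gene and all probe sets counted singly. Further ones were a replicate block, only the 4 arrays compared, a minimum change of 2-fold and leaving out each of the 10 arrays. The scalings, the pseudocounts and the fits without an array kept the genes and probe sets chosen on all 10 arrays. Where an array was left out, the remaining array of that time was assumed to vary like the other groups.

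The procedure was tested on simulated data, in which 200 genes of the comparison of 8 h with 0 h were changed in each of 5 rounds. It recovered 44% of 2-fold and 78.4% of 4-fold changes, and 5.58% of the calls were false. The real comparison called 3098 genes, a far larger share, so this recovery need not carry over. The noise was drawn as the model assumes, so the share of false calls does not test those assumptions. Recovery of 2-fold changes ran from 3.94% in the dimmest of 4 equal brightness groups of genes to 90.2% in the brightest. For 4-fold changes the same groups gave 48.2% and 92.9%. A recovery limit set beforehand for 4-fold changes was not met. The misses were then traced to dim genes, to 4.2% of changed genes that the filter removed and to 6.3% whose change was carried by another probe set. On the scale of log2(signal + 16), on which the changes were simulated, the median ratio of estimate to truth was 1. This median was pooled over brightness and left out the changes lost to the filter or carried by another probe set. The limit was replaced by a test of correctness. A simulated list of 25 genes shifted by a log2 value of 0.7 was called in 5 of 5 rounds by all 3 list tests, and 0 of 150 unshifted lists were called by camera with either correlation or by fry. Noise was drawn independently for each probe set, so these lists do not test camera on genes that move together.

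Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.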

Results

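Human primary fibroblasts that had been starved of serum for 48 h were measured at 0, 2, 4, 6 and 8 h after serum was given back. Each of the 5 times was represented by 2 arrays from independent biological replicates, 10 arrays in all, and 12998 genes were tested. Across genes, the log2 signals of the arrays of one time correlated with r from 0.942 to 0.965, and genes are not independent replicates. Arrays of different times correlated with r from 0.876 to 0.963, so the ranges overlapped. The array 8 h replicate 2 correlated more with an array of another time (0.9626) than with its partner (0.9592). The first principal component carried 35.6% of the variance and the second 17.6%. The median signal of an array ran from 31.6 (4 h replicate 1) to 48.8 (2 h replicate 2). The ratio of 3' to 5' signal, a sign of RNA integrity, lay between 0.911 and 1.26 for GAPDH and between 0.981 and 1.17 for beta-actin. The control probe sets for 18S ribosomal RNA had a geometric mean signal of 307 in 0 h replicate 2 and 288 in 4 h replicate 1. The other 8 arrays had 60.9 to 134.

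All 10 fibroblast markers lay above the median brightness of the probe sets, with a median signal of 11600, and COL1A1, COL1A2 and VIM were among the brightest genes. The median signal was 28.8 for adipocyte markers, 29.8 for endothelial, 24.9 for epithelial, 23.5 for leukocyte and 47.6 for melanocyte markers. Among the epithelial markers, KRT10 and KRT19 stood apart with mean signals at 0 h of 1777 and 1421. Smooth muscle markers had a median signal of 164. Signals of different probe sets are not comparable as amounts of RNA, so these levels give no shares of cell types. Of their 6 tested members, 3 (DES, CNN1 and SMTN) rose at 2 h, 4 h, 6 h and 8 h, and CNN1 is also in the list of SRF and MRTF genes. The list was called up at all 4 times (camera adjusted p 0.00124, 0.00541, 0.00206 and 0.00386, adjusted p = 0.35 at each with an estimated correlation). Fibroblast markers, 5 of which are also in the list of collagens and matrix, were called down at 2 h with 0 of 10 genes past the threshold (camera adjusted p 0.017, adjusted p = 0.35 with an estimated correlation, and 0.873 under quantile normalization). Of the 10, 5 fell at 6 h and 5 at 8 h (camera adjusted p 0.00148 and 0.00964, adjusted p = 0.35 for both with an estimated correlation), and 4 and 5 fell under quantile normalization (0.0139 and 0.0291) but 7 and 2 with a common median per array (0.000608 and 0.0118). No other marker list was called in a comparison with 0 h. At 8 h the camera adjusted p was 0.773 for epithelial markers, 0.931 for leukocyte markers, and 0.91 for endothelial, melanocyte and adipocyte markers alike.

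The comparison of 2 h with 0 h asked which transcripts had changed soon after serum was returned. Where the dimmer mean signal of a gene lay under the filter level of 36.92, its change is given as "at least". Lower signals were raised to that level, and the spread between arrays is not allowed for. FOSB, a subunit of the AP-1 transcription factor, rose at least 173-fold, from a mean signal of 6.45 to 9193 (limma log2 change without the bound 8.67, SE 0.42, n = 2 arrays at each time). IL11, a cytokine of the interleukin-6 family, rose 85.1-fold (SE 0.27), ID1, an inhibitor of basic helix-loop-helix factors, 74.5-fold (SE 0.14), and HBEGF, a ligand of the EGF receptor, 39.1-fold (SE 0.22). ARC and CLDN4 rose at least 31.1-fold and 13.5-fold from signals of 8.75 and 5.95. The largest fall was that of DDIT4, an inhibitor of mTORC1 signalling, with a log2 change of -4.05 (SE 0.34). CDKN1B, which encodes the cyclin-dependent kinase inhibitor p27, fell by 2.58 on the log2 scale (SE 0.24), and TXNIP, a repressor of glucose uptake, fell by 2.47 (SE 0.23).

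Of the 29 immediate early transcription factors measured, 22 rose, 0 fell and 7 did not pass the test at 2 h (25 rose when adjusted over the list alone; camera adjusted p 9.87e-45). JUNB rose 47.9-fold, EGR3 36-fold and the nuclear receptor NR4A1 67.9-fold. EGR1 rose 4.74-fold and SRF, the serum response factor, 3.13-fold, whereas FOS had a log2 change of 1.94 with an SE of 0.77 (adjusted p 0.176). MYC rose 3.1-fold and CCND1, which encodes cyclin D1, 2.32-fold. Feedback inhibitors of growth factor signalling rose in 10 of 20 cases, with 1 fall and 9 not past the threshold (12 rose and 2 fell when adjusted over the list alone; camera adjusted p 5.69e-12). The MAP kinase phosphatases DUSP2, DUSP5 and DUSP1 rose at least 6.98-fold, 11.9-fold and 11.8-fold, and SOCS3, an inhibitor of cytokine receptors, 9.85-fold.

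Cytokines and chemokines and the TGF beta and BMP list were also called up early. At 2 h, 9 of 22 cytokines and chemokines rose and 13 did not pass (12 rose when adjusted over the list alone, camera adjusted p 1.9e-13). Among them were LIF (at least 28.7-fold), PTGS2, the inducible cyclooxygenase (16.8-fold), CXCL8 (12.1-fold, SE 0.5) and IL6 (5.85-fold). The 0 h arrays differed widely for CXCL8 (mean signal 54.15, SD 46.5) and LIF (29.3, SD 35.2). The folds of both at this and later times are uncertain, and the bound for LIF does not allow for this spread. In the list of TGF beta and BMP response, 9 of 17 rose, 0 fell and 8 did not pass (11 rose when adjusted over the list alone; camera adjusted p 1.27e-14), with ID3 at 28.4-fold, ID4 at 12.2-fold and the inhibitory SMAD7 at 10.3-fold. These 4 lists kept their call with an estimated correlation.

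For 5 further lists the call at 2 h was up and was lost with an estimated correlation. Secreted growth factors had 4 of 19 up and 15 not past, including VEGFA (6.15-fold) and PDGFA (5.48-fold), with 6 up when adjusted over the list alone (camera adjusted p 6.9e-05, adjusted p = 0.114 with an estimated correlation). Ribosome biogenesis had 4 of 32 up and 28 not past, such as the helicase DDX21 (2.17-fold), and 7 up and 1 down when adjusted over the list alone (camera adjusted p 7.92e-05, adjusted p = 0.0626 with an estimated correlation). Targets of YAP and TEAD rose in 5 of 14 cases and 9 did not pass, with F3, the tissue factor, at 4.52-fold, CCN2 at 2.57-fold and CCN1 at 2.36-fold (6 up when adjusted over the list alone; camera adjusted p 0.00197, adjusted p = 0.073 with an estimated correlation). Cytoskeletal genes under SRF and MRTF had 4 of 22 up and 18 not past, with FILIP1L at 2.8-fold and CNN1 at 2.01-fold, and 8 up and 1 down when adjusted over the list alone (camera adjusted p 0.00692, adjusted p = 0.157 with an estimated correlation). Proteases and wound remodelling had 3 of 21 up, 1 down and 17 not past, with PLAUR, the urokinase receptor, at 7.59-fold and EDN1, endothelin 1, at 6.69-fold (6 up and 1 down when adjusted over the list alone; camera adjusted p 0.0218, adjusted p = 0.124 with an estimated correlation).

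The lists called down at 2 h were cytosolic ribosomal proteins, oxidative phosphorylation, amino acid and ER stress response, and nuclear import and tRNA synthetases. Of 15 ribosomal protein genes, 0 passed the test over all genes and 11 fell when adjusted over the list alone (camera adjusted p 9.88e-06, adjusted p = 0.227 with an estimated correlation, and 0.426 under quantile normalization). For oxidative phosphorylation, 2 of 20 fell, SDHC and UQCRB, and 18 did not pass, with 1 up and 7 down when adjusted over the list alone (camera adjusted p 0.00145, adjusted p = 0.135 with an estimated correlation). In the stress response list DDIT4 fell, SLC7A5, an amino acid transporter, rose 2.02-fold and 20 of 22 did not pass, with 1 up and 6 down when adjusted over the list alone (camera adjusted p 0.00475, adjusted p = 0.164 with an estimated correlation). IARS1 and GARS1 were the 2 of 19 members that fell in the synthetase list, beside 17 not past and 6 down when adjusted over the list alone (camera adjusted p 0.00951, adjusted p = 0.126 with an estimated correlation, and 0.101 under quantile normalization). CCNE1, CCNE2 and E2F1, genes of the G1 to S transition, had limma adjusted p values of 0.88, 0.825 and 0.864. With mean signals of 89.9, 37.7 and 71.1 at 2 h they were dim, so a change could have been missed.

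In total 469 genes rose and 204 fell at 2 h, 5.18% of those tested, 342 and 74 of them by at least 2-fold. With each array scaled to a common median, 354 rose and 78 fell, so the share of falls was 18.1% in place of 30.3%. Leaving out 1 array moved the total of 673 to 441 without 0 h replicate 1, to 341 without 0 h replicate 2 and to 421 without 2 h replicate 2, with 70, 38 and 62 falls. Without 2 h replicate 1, 459 rose and 428 fell, so the balance of rises and falls at 2 h depended on single arrays. CCDC85B was among the 10 largest falls (log2 change -2.08, SE 0.24), but its 2 probe sets moved in opposite directions.

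**Figure D1:**
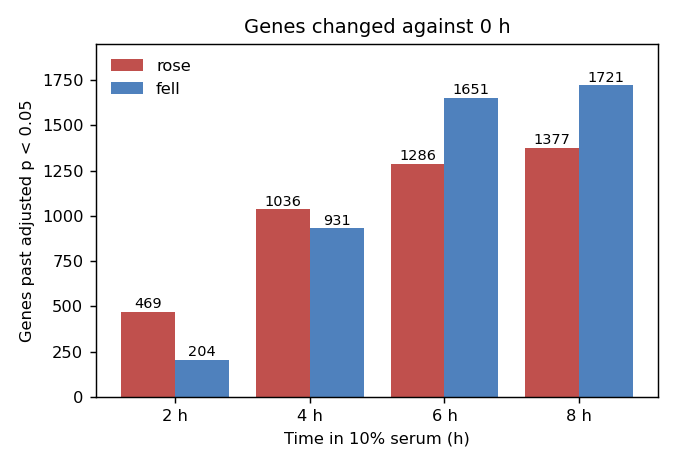
Number of genes that rose and fell in each comparison with 0 h at a limma adjusted p under 0.05, of 12998 tested, with 2 arrays at each time. The totals ran from 673 at 2 h to 3098 at 8 h.

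The comparison of 4 h with 0 h asked what followed the first wave. IL11 rose 120-fold (log2 change 6.91, SE 0.27, n = 2 arrays at each time), PTGS2 77-fold (SE 0.28) and HAS2, which makes hyaluronan, at least 63.4-fold. CCL2, a chemokine for monocytes, rose 42.6-fold (SE 0.24) and CD274, which encodes the immune checkpoint ligand PD-L1, 41.3-fold (SE 0.31). FOSB was still at least 13.1-fold above 0 h, with a mean signal of 689. OSR2, a zinc finger transcription factor, showed the largest fall, with a log2 change of -4.88 (SE 0.26) and a mean signal of 155 after 4953 at 0 h. GAS1, a gene named for its expression in growth arrest, fell by 3.25 on the log2 scale (SE 0.24), KLF4 fell by 3.1 (SE 0.31), and TCF7L2, a transcription factor of the Wnt pathway, fell by 2.97 (SE 0.22) with all 6 of its probe sets down.

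At 4 h, 19 of 22 cytokines and chemokines rose and 3 did not pass (20 rose when adjusted over the list alone; camera adjusted p 1.09e-24), including CXCL8 (118-fold), LIF (at least 37.8-fold) and IL6 (12.6-fold). Feedback inhibitors had 17 of 20 up, 0 down and 3 not past (17 up and 1 down when adjusted over the list alone; camera adjusted p 3.07e-19), with SPRY4, which dampens receptor tyrosine kinase signalling, at 18.3-fold and ERRFI1, an inhibitor of the EGF receptor, at 12.8-fold. Of the 29 immediate early factors, 21 were above 0 h, 1 below and 7 not past, with the same 3 counts when adjusted over the list alone (camera adjusted p 4.17e-18), such as FOSL1 (13.7-fold), NR4A3 (at least 5.37-fold) and MAFF (8.69-fold). EGR1 rose 2.16-fold and JUNB 3.76-fold, and FOS had a log2 change of -0.51 (adjusted p 0.722). Proteases and wound remodelling had 12 of 21 up, 2 down and 7 not past (12 up and 3 down when adjusted over the list alone; camera adjusted p 1.02e-05), with PLAUR at 9.45-fold and the collagenase MMP1 at 4.63-fold.

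Ribosome biogenesis became one of the clearest groups at 4 h: 23 of 32 rose, 0 fell and 9 did not pass (27 rose when adjusted over the list alone; camera adjusted p 9.1e-20). RRS1 rose 6.08-fold, RRP9 5.49-fold, NIP7 5.42-fold and NOP16 5.2-fold, all nucleolar factors of ribosome assembly. In the list of TGF beta and BMP response, 6 of 17 were above 0 h, 2 below and 9 not past (9 up and 2 down when adjusted over the list alone; camera adjusted p 9.11e-05), with ID1 at 17.7-fold, ID3 at 11.9-fold and SMAD6 at a log2 change of -2.19. FOXO targets and other quiescence genes were the list called down that kept its call with an estimated correlation: 2 of 24 rose, 11 fell and 11 did not pass (2 up and 15 down when adjusted over the list alone; camera adjusted p 0.000214). TXNIP fell by 3.83 on the log2 scale and FBXO32, a ubiquitin ligase of atrophy, fell at least 2.88-fold, while FOXO3 itself rose 3.08-fold.

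The remaining lists called at 4 h lost the call with an estimated correlation. Up were secreted growth factors (11 of 19 rose, 1 fell and 7 did not pass; 12 and 1 when adjusted over the list alone), with INHBA at 7.59-fold and BMP2 at 5.89-fold or more (camera adjusted p 2.61e-08, adjusted p = 0.0531 with an estimated correlation). Cytosolic chaperones had 11 of 16 up and 5 not past, with HSPH1 at 4.9-fold and DNAJA1 at 2.35-fold, and 12 up when adjusted over the list alone (camera adjusted p 5.52e-10, adjusted p = 0.0626 with an estimated correlation). Splicing and mRNA export had 4 of 21 up and 17 not past, with SRSF7 at 2.76-fold and HNRNPAB at 2.74-fold, and 7 up when adjusted over the list alone (camera adjusted p 5.67e-05, adjusted p = 0.157 with an estimated correlation). MYC metabolic and translation targets had 6 of 20 up, 1 down and 13 not past, with the cap-binding protein EIF4E at 2.48-fold, and 7 up and 1 down when adjusted over the list alone (camera adjusted p 0.00227, adjusted p = 0.124 with an estimated correlation). Cytoskeletal genes under SRF and MRTF (6 of 22 up, 1 down and 15 not past; 8 and 2 when adjusted over the list alone) had a camera adjusted p of 0.000546 (adjusted p = 0.103 with an estimated correlation). Glycolysis and hypoxia had 5 of 22 up, with hexokinase HK2 at 3.93-fold, 1 down and 16 not past, the same when adjusted over the list alone (camera adjusted p 0.0163, adjusted p = 0.157 with an estimated correlation). G1 cyclins and kinases had 3 of 10 up and 7 not past, in both adjustments: CCND1 rose 4.33-fold, CCND3 1.49-fold and CDK6 1.48-fold (camera adjusted p 0.0492, adjusted p = 0.157 with an estimated correlation, and 0.059 under quantile normalization).

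Growth arrest specific genes were called down at 4 h, with 1 of 12 up, 7 down and 4 not past (2 up and 8 down when adjusted over the list alone; camera adjusted p 0.00418, adjusted p = 0.139 with an estimated correlation). Besides GAS1, the transcriptional repressor HBP1 fell by 1.74 on the log2 scale. CDK inhibitors and pocket proteins had 4 of 9 down and 5 not past, in both adjustments, with CCNG2, a cyclin of quiescent cells, at -2.48 and CDKN1B at -2.31 (camera adjusted p 0.0104, adjusted p = 0.284 with an estimated correlation). In the amino acid and ER stress list 2 of 22 rose, 10 fell and 10 did not pass (3 up and 12 down when adjusted over the list alone; camera adjusted p 0.00951, adjusted p = 0.188 with an estimated correlation), with DDIT4 at -4.27, CHAC1, a target of ATF4 that degrades glutathione, at -2.66 and ATF4 itself at -1.27.

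At 4 h, 1036 genes rose and 931 fell, 15.1% of those tested, 590 and 401 of them by at least 2-fold. The median log2 change of all genes was -0.151, against -0.00615 with a common median per array and -0.102 under quantile normalization. Scaling to a common median gave 977 rises and 356 falls, so the share of falls was 26.7% in place of 47.3%. The total of 1967 became 1128 without 0 h replicate 1, 1068 without 0 h replicate 2 and 1084 without 4 h replicate 1, the array with the lowest median signal, with 384, 360 and 455 falls.

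**Figure D2:**
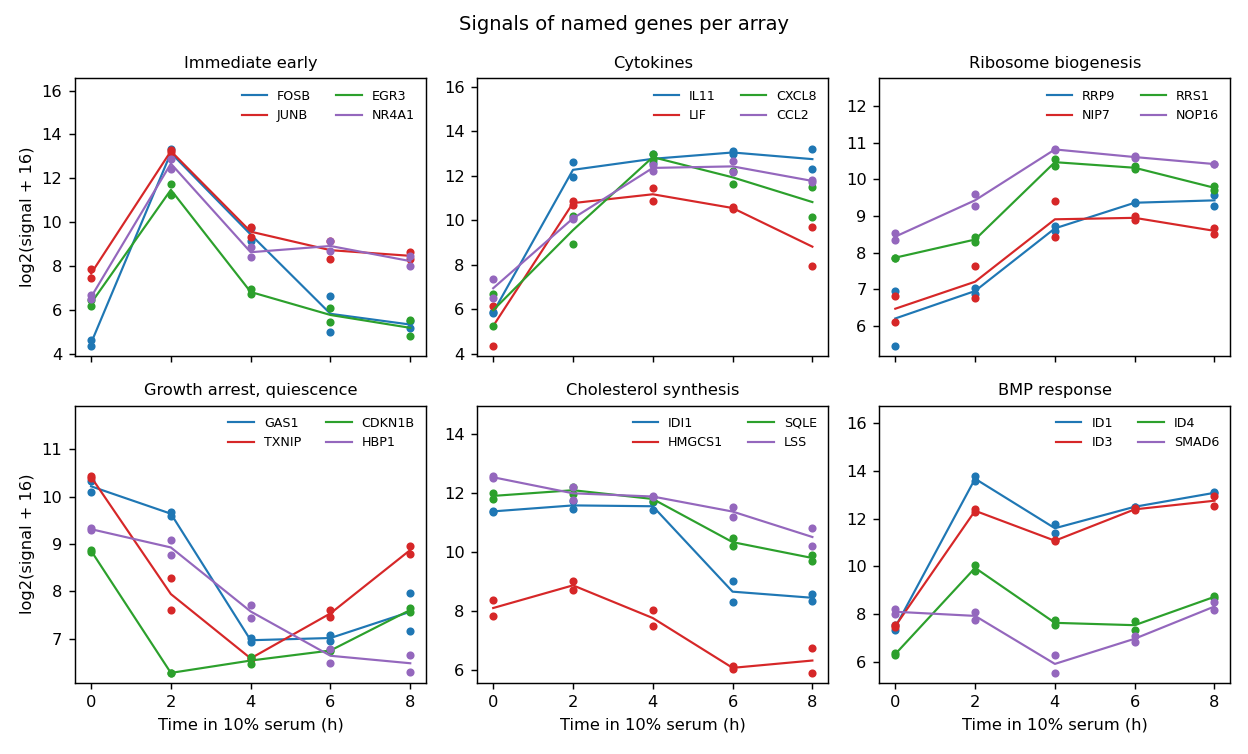
log2(signal + 16) over the hours after serum for named genes of 6 groups, with a point for each array and a line through the group means (n = 2). FOSB, JUNB, EGR3 and NR4A1 peaked at 2 h, RRP9, NIP7, RRS1 and NOP16 rose by 4 h, IDI1, HMGCS1, SQLE and LSS were lower at 6 h and 8 h than at 0 h, and ID1, ID3, ID4 and SMAD6 were lower at 4 h than at 2 h and 8 h.

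The comparison of 6 h with 0 h brought the cholesterol pathway into view. IDI1, which makes the isoprenoid building block dimethylallyl diphosphate, fell by 2.71 on the log2 scale, from a mean signal of 2648 to 402 (SE 0.21, n = 2 arrays at each time). HMGCS1, an early enzyme of the mevalonate pathway, fell by 2.02 (SE 0.32), TMEM97 fell by 1.81 (SE 0.12) and SQLE, squalene epoxidase, fell by 1.56 (SE 0.15). Among the largest rises were IL11 at 146-fold (SE 0.27), TFPI2, a serine protease inhibitor, at 45-fold (SE 0.41) and CCL2 at 44.7-fold (SE 0.24). OSR2 again showed the largest fall, with a log2 change of -5.18 (SE 0.26).

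Cholesterol synthesis and uptake had 1 of 20 genes up, 15 down and 4 not past at 6 h (1 up and 18 down when adjusted over the list alone; camera adjusted p 1.94e-08), and the call held with an estimated correlation. Fatty acid synthesis had 5 of 12 down and 7 not past, in both adjustments, with the desaturase SCD at -1.14 and SREBF1, a regulator of lipid synthesis, at -1.01 (camera adjusted p 0.00501, adjusted p = 0.145 with an estimated correlation). FOXO targets and quiescence genes had 1 of 24 up, 14 down and 9 not past (1 and 20 when adjusted over the list alone; camera adjusted p 3.76e-07), a call that held with an estimated correlation. TXNIP fell by 2.88, TSC22D3, a glucocorticoid-induced gene, fell by 1.67 and YPEL3 fell by 1.65. The growth arrest specific list had 1 of 12 up, 7 down and 4 not past (1 and 9 when adjusted over the list alone; camera adjusted p 7.87e-05, adjusted p = 0.0712 with an estimated correlation), with GAS1 at -3.2, HBP1 at -2.67 and the PDGF receptor PDGFRA at -1.72. CDK inhibitors and pocket proteins had 5 of 9 down and 4 not past, in both adjustments (camera adjusted p 0.00154, adjusted p = 0.199 with an estimated correlation), such as CDKN1C at -1.71 and CDKN2B, which fell at least 2.62-fold. In the list of collagens and matrix, 2 of 26 rose, 12 fell and 12 did not pass (2 and 15 when adjusted over the list alone; camera adjusted p 0.000856, adjusted p = 0.199 with an estimated correlation). ELN, which encodes elastin, rose 8.03-fold, whereas COL12A1 fell by 0.79 and FBLN1 fell by 0.73 on the log2 scale. Ribosomal proteins had 4 of 15 down and 11 not past (8 down when adjusted over the list alone; camera adjusted p 0.000984, adjusted p = 0.343 with an estimated correlation, and 0.859 under quantile normalization). Nuclear import and tRNA synthetases had 3 of 19 up, 10 down and 6 not past (3 and 11 when adjusted over the list alone; camera adjusted p 0.0156, adjusted p = 0.139 with an estimated correlation). The importin IPO7 rose 1.88-fold, and AARS1 fell by 1.11 on the log2 scale.

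Several groups stayed up at 6 h. Ribosome biogenesis had 25 of 32 up and 7 not past (27 up when adjusted over the list alone; camera adjusted p 5.76e-17), with RRP9 at 8.92-fold, and cytokines and chemokines had 19 of 22 up and 3 not past (20 up when adjusted over the list alone; camera adjusted p 3.57e-18), with CXCL8 at 63-fold and IL6 at 16-fold. Feedback inhibitors had 13 of 20 up, 1 down and 6 not past, in both adjustments (camera adjusted p 2.16e-11), and proteases and wound remodelling 12 of 21 up, 4 down and 5 not past (12 and 5 when adjusted over the list alone; camera adjusted p 8.91e-05). The TGF beta and BMP list had 9 of 17 up, 2 down and 6 not past, in both adjustments (camera adjusted p 0.000236), with ID1 at 33-fold and ID3 at 29.6-fold. Immediate early factors had 16 of 29 up, 1 down and 12 not past (18 and 2 when adjusted over the list alone; camera adjusted p 3.87e-07), with FOSL1 at 10.7-fold and KLF4 at a log2 change of -3.57. These 6 calls held with an estimated correlation. Those of secreted growth factors (10 of 19 up and 3 down; camera adjusted p 2e-05), chaperones (10 of 16 up and 0 down; 1.44e-06), splicing (6 of 21 up and 0 down; 0.000758) and MYC targets (10 of 20 up and 3 down; 0.00492) did not (adjusted p = 0.0993, 0.11, 0.209 and 0.139 with an estimated correlation). Adjusted over the list alone, these 4 lists had 12, 11, 10 and 11 genes up and 3, 0, 0 and 4 down. CCND1 rose 6.66-fold and MYC 1.93-fold, and EGR1 had a log2 change of -0.29 (adjusted p 0.625).

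At 6 h, 1286 genes rose and 1651 fell, 22.6% of those tested, 674 and 722 of them by at least 2-fold. With a common median per array 921 rose and 1223 fell. Without either of the 0 h arrays, however, called rises and falls were about equal in number, so the excess of falls at 6 h depended on having both. The total of 2937 became 1702 without 0 h replicate 2, 1778 without 6 h replicate 1 and 1753 without 6 h replicate 2.

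The comparison of 8 h with 0 h covered the latest time. IL11 was 119-fold above 0 h (log2 change 6.89, SE 0.27, n = 2 arrays at each time), TFPI2 59.7-fold (SE 0.41) and IL33, an alarmin cytokine, at least 15.5-fold. TM4SF1, a membrane protein with 4 transmembrane segments, rose 33.5-fold (SE 0.31) and NEFM, a neurofilament subunit, at least 19.5-fold. CCND1 rose 5.9-fold (SE 0.17) and CCND3 2.87-fold (SE 0.15). Among the largest falls were OSR2 (log2 change -4.37, SE 0.26), the sugar transporter SLC2A12 (at least 6.57-fold, to a signal of 9.45), TCF7L2 (-3.02, SE 0.22) and SLC7A11, the cystine transporter (-2.84, SE 0.2).

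At 8 h, 17 of 20 genes of cholesterol synthesis and uptake had fallen, 0 had risen and 3 did not pass (1 up and 18 down when adjusted over the list alone; camera adjusted p 7.88e-11). IDI1 stood at a log2 change of -2.92, SQLE at -2.1 and LSS, lanosterol synthase, at -2.02. Ribosome biogenesis had 24 of 32 up, 0 down and 8 not past (25 up when adjusted over the list alone; camera adjusted p 6.79e-17), with RRP9 at 9.33-fold. Cytokines and chemokines had 15 of 22 up and 7 not past (16 up when adjusted over the list alone; camera adjusted p 5.44e-13), and proteases and wound remodelling 12 of 21 up, 1 down and 8 not past, with the matrix protein TNC at 5.65-fold (13 and 2 when adjusted over the list alone; camera adjusted p 6.19e-06). In the TGF beta and BMP list 10 of 17 rose, 2 fell and 5 did not pass (11 and 2 when adjusted over the list alone; camera adjusted p 1.87e-06), with ID1 at 49.5-fold and ID3 at 38.1-fold. FOXO targets and quiescence genes had 1 of 24 up, 15 down and 8 not past (1 and 16 when adjusted over the list alone; camera adjusted p 3.88e-05), with YPEL3 at -2.21 and the insulin receptor INSR, which fell at least 3.42-fold. These 6 calls held with an estimated correlation.

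Cell cycle genes moved in part at 8 h. CDK inhibitors and pocket proteins had 1 of 9 up, 7 down and 1 not past (1 and 8 when adjusted over the list alone; camera adjusted p 0.000207, adjusted p = 0.157 with an estimated correlation), with CDKN1C at a log2 change of -2.46, CDKN1B at -1.25 and CDKN2B, which fell at least 2.71-fold. G1 cyclins and kinases had 2 of 10 up, CCND1 and CCND3, and 8 not past, in both adjustments (camera adjusted p 0.0395, adjusted p = 0.156 with an estimated correlation). In the list of DNA replication and E2F targets 3 of 25 rose and 22 did not pass, in both adjustments (camera adjusted p 0.0215, adjusted p = 0.324 with an estimated correlation, and 0.0556 by fry). That call was lost without 8 h replicate 1 (adjusted p 0.269, 2 genes up). The 3 were UHRF1 (3.57-fold), which maintains DNA methylation at replication forks, the flap endonuclease FEN1 (2.12-fold) and the ribonucleotide reductase subunit RRM2 (1.86-fold). CCNE1, CCNE2 and E2F1 had limma adjusted p values of 0.838, 0.632 and 0.645. Their mean signals at 8 h were 126, 69.9 and 74.35 with SDs of 82.4, 33.9 and 68.2, so a change could have been missed. Mitotic genes had 0 of 14 past the threshold in either adjustment (camera adjusted p 0.92), with AURKA at a log2 change of 1.25 (adjusted p 0.0535).

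Other lists called up at 8 h were chaperones (11 of 16 up, 0 down; camera adjusted p 4.01e-07), feedback inhibitors (10 of 20 up, 2 down; 6.34e-06), splicing and mRNA export (13 of 21 up, 1 down; 2.77e-06), MYC targets (11 of 20 up, 3 down; 0.000522), secreted growth factors (10 of 19 up, 3 down; 0.00175), immediate early factors (11 of 29 up, 4 down; 0.00623) and SRF and MRTF genes (10 of 22 up, 3 down; 0.0157). With an estimated correlation their adjusted p values were 0.0993, 0.0712, 0.135, 0.0983, 0.157, 0.157 and 0.174. Adjusted over the list alone, 11, 11, 13, 11, 11, 12 and 10 genes rose. SRM, spermidine synthase, rose 2.89-fold, ACTG2, a smooth muscle actin, 2.86-fold and SRSF7 3.44-fold. EGR1, MYC and SRF had log2 changes of 0.04, 0.46 and -0.09 (adjusted p 0.955, 0.0636 and 0.839). Lists called down were growth arrest specific genes (9 of 12 down, 1 up; camera adjusted p 2.17e-05), fatty acid synthesis (6 of 12 down, 1 up; 0.0135), collagens and matrix (8 of 26 down, 2 up; 0.0434) and ribosomal proteins (3 of 15 down, 0 up; 0.0442). Their adjusted p values were 0.0626, 0.164, 0.406 and 0.558 with an estimated correlation, and under quantile normalization collagens had an adjusted p of 0.13 and ribosomal proteins of 0.548. Adjusted over the list alone, 9, 8, 9 and 3 genes fell. HBP1 fell by 2.83 on the log2 scale, and RPL3 fell by 0.51.

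In total, 1377 genes rose and 1721 fell at 8 h, 23.8% of those tested, 680 and 805 of them by at least 2-fold. With a common median per array 1075 rose and 1086 fell (50.3% falls in place of 55.6%). Without either of the 0 h arrays called rises and falls were also nearly equal in number, so the excess of falls at 8 h depended on these choices. The total of 3098 became 1888 without 0 h replicate 2 and 2007 without 8 h replicate 2.

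**Figure D3:**
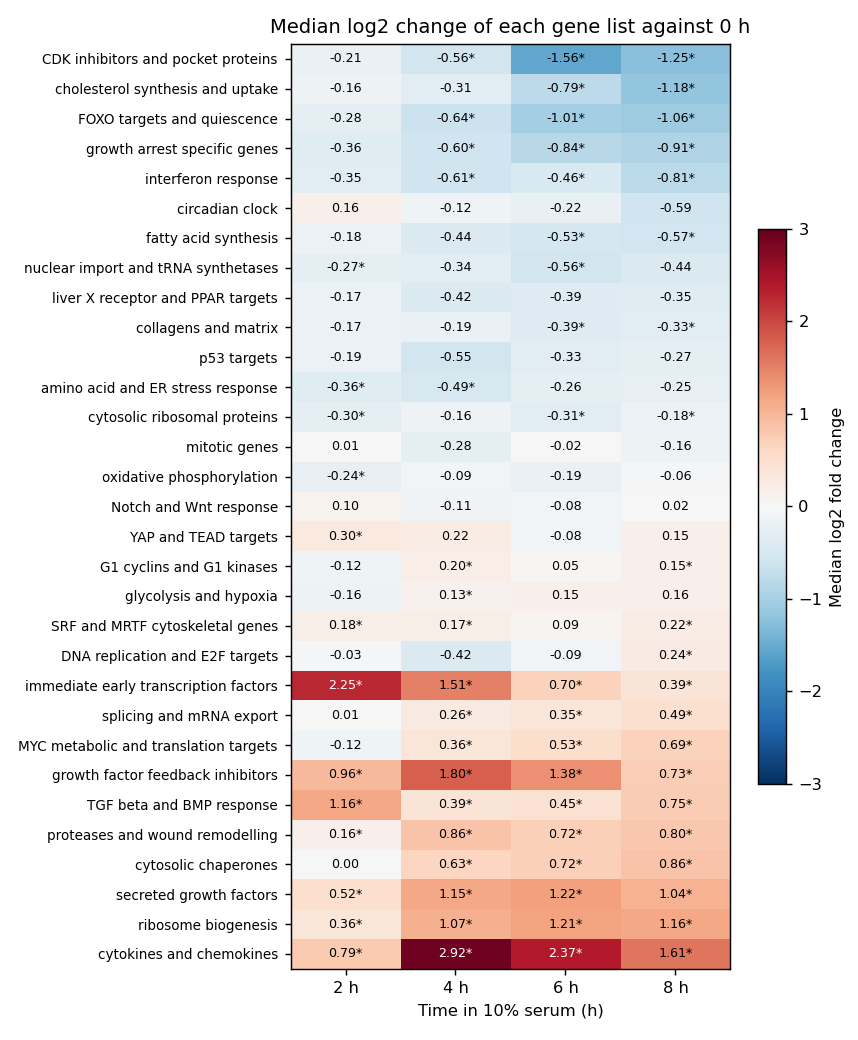
Median log2 change of each of the 31 gene lists against 0 h at 2, 4, 6 and 8 h, sorted by the value at 8 h. An asterisk marks a camera adjusted p under 0.05 at the preset correlation, and the calls lost with an estimated correlation are named in the text.

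The interval comparisons asked when each change took place. From 2 h to 4 h, EGR3 fell by 4.66 on the log2 scale (SE 0.34, n = 2 arrays at each time), KLF4 fell by 3.92 (SE 0.31) and JUNB fell by 3.67 (SE 0.25). Over the same 2 h CCL20, a chemokine for dendritic cells and lymphocytes, rose at least 7.83-fold from a signal of 3.2, HAS2 21.4-fold (SE 0.3) and the ERK phosphatase DUSP6 17.2-fold (SE 0.31). Immediate early factors had 2 of 29 up, 15 down and 12 not past in this interval (camera adjusted p 3.04e-13, adjusted p = 0.0516 with an estimated correlation). Ribosome biogenesis had 19 of 32 up and 13 not past, a call that held (camera adjusted p 8.7e-17; 0.0392 with an estimated correlation), and cytokines had 14 of 22 up and 8 not past (camera adjusted p 7.21e-12, adjusted p = 0.0674 with an estimated correlation). The TGF beta and BMP list had 1 of 17 up, 8 down and 8 not past (camera adjusted p 1.14e-05, adjusted p = 0.0516 with an estimated correlation), with TGIF1 at -2.64 and ID1 at -2.07. Adjusted over the list alone, these 4 lists had 2, 22, 15 and 2 genes up and 18, 0, 2 and 9 down. Over the 31 lists camera called 11 up and 5 down, and 1 and 0 with an estimated correlation. In all 632 genes rose and 586 fell, 244 and 375 of them by at least 2-fold, and with a common median per array 554 rose and 280 fell (33.6% falls in place of 48.1%). The total of 1218 became 374 without 4 h replicate 1 (165 rose and 209 fell) and 473 without 2 h replicate 2. Without the variance trend 250 rose and 326 fell, so the direction with more genes depended on these choices.

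From 4 h to 6 h camera called 0 lists up and 10 down, and 0 with an estimated correlation. The smallest p was that of cholesterol synthesis, with 0 of 20 up, 7 down and 13 not past (9 down when adjusted over the list alone; camera adjusted p 6.78e-13, adjusted p = 0.0516 with an estimated correlation). IDI1 fell by 2.89 on the log2 scale (SE 0.21, n = 2 arrays at each time), INSIG1, a sterol sensor of the endoplasmic reticulum, fell by 1.61 (SE 0.31) and SQLE fell by 1.46 (SE 0.15). FOSB fell by 3.62 (SE 0.42) and DUSP6 fell by 2.41 (SE 0.31), while GATA3, a transcription factor, rose at least 1.81-fold from a signal of 6.2 and ATOH8 3.41-fold (SE 0.25). In this interval 64 genes rose and 166 fell, 39 and 98 of them by at least 2-fold, and with a common median per array 12 rose and 161 fell (93.1% falls in place of 72.2%). The total of 230 became 49 without 4 h replicate 1, 84 without 4 h replicate 2, 48 without 6 h replicate 1 and 58 without 6 h replicate 2.

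Few genes passed the threshold from 6 h to 8 h: 8 rose and 10 fell, while 1000 had an unadjusted p under 0.05. By camera 11 lists were called up and 6 down in this interval, and 0 with an estimated correlation. MBNL2, a splicing regulator, rose 2.95-fold (SE 0.2, n = 2 arrays at each time), FARSB, a subunit of phenylalanyl-tRNA synthetase, 2.72-fold (SE 0.2) and TXNIP 2.53-fold (SE 0.23). ERRFI1 fell by 1.73 on the log2 scale (SE 0.2), DUSP6 fell by 1.77 (SE 0.31) and HBEGF fell by 1.29 (SE 0.22). TXNIP, DUSP6 and HBEGF each had a limma adjusted p of 0.0499, just under the threshold. With all probe sets tested singly, 0 of 3, 0 of 2 and 0 of 3 passed for DUSP6, HBEGF and TXNIP. By that count 1 of 5 passed for MBNL2, and 1 of 1 for FARSB and for ERRFI1. DNA replication and E2F targets had 0 of 25 past the threshold in either adjustment and a median log2 change of 0.356 (camera adjusted p 7.68e-06, adjusted p = 0.155 with an estimated correlation). Under quantile normalization 6 genes rose and 12 fell (66.7% falls in place of 55.6%). The limma total was 0 without 6 h replicate 1, 6 h replicate 2 or 8 h replicate 1, where 792, 642 and 736 genes had an unadjusted p under 0.05, and it was 28 without 2 h replicate 2.

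Between 2 h and 8 h, FOSB fell at least 173-fold (n = 2 arrays at each time), EGR3 at least 53.7-fold and ARC at least 31.1-fold, and ATF3 fell by 4.5 on the log2 scale (SE 0.28), all genes of the early response. IL33 rose at least 15.5-fold, TFPI2 26.3-fold (SE 0.41) and TM4SF1 19.1-fold (SE 0.31). Immediate early factors had 1 of 29 up, 24 down and 4 not past (1 and 25 when adjusted over the list alone; camera adjusted p 3.8e-22; 0.0392 with an estimated correlation). Cholesterol synthesis had 0 of 20 up, 14 down and 6 not past (17 down when adjusted over the list alone; camera adjusted p 2.67e-11, adjusted p = 0.0516 with an estimated correlation), and ribosome biogenesis 24 of 32 up and 8 not past (26 up when adjusted over the list alone; camera adjusted p 6.78e-13, adjusted p = 0.0505 with an estimated correlation). Camera called 10 lists up and 7 down, and 0 and 1 with an estimated correlation. In total 1360 genes rose and 1374 fell, 563 and 740 of them by at least 2-fold. The total of 2734 became 1737 without 8 h replicate 1.

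Across the 5 times, 3598 genes (27.7%) changed by limma's F test. By group mean, 1247 of them were highest at 0 h, 672 at 2 h, 452 at 4 h, 389 at 6 h and 838 at 8 h. Neighbouring times shared many calls: 338 genes rose and 94 fell at both 2 h and 4 h (37.4 and 14.6 expected from independent draws), 827 rose and 692 fell at both 4 h and 6 h (103 and 118), and 1066 rose and 1256 fell at both 6 h and 8 h (136 and 219). Between 2 h and 8 h, 266 shared rises and 95 shared falls stood against 49.7 and 27. In 100 simulated data sets without any effect, in which the comparisons also shared their 0 h arrays, each of these counts had a median of 0 and was at most 1. The simulated counts leave out real effects and the independent draws leave out the shared 0 h arrays, so part of each excess may come from these arrays.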

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

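The comparison of 2 h with 8 h was planned before the data were examined, whereas the count of genes with opposite changes and the test of probe sets without a single gene name were chosen after the first results were seen. Against 0 h, 19 genes were higher at 2 h and lower at 8 h, and 10 genes were lower at 2 h and higher at 8 h, each with a difference between 2 h and 8 h past the threshold in limma (n = 2 arrays at each time), which their selection all but fixes. Among the 19, EGR3, an early growth response factor, stood at log2 changes of 5.17 and -1.13 (-6.29 from 2 h to 8 h), the kinase PIM1 at 2.33 and -0.97 (-3.3), and MNT, an antagonist of MYC, at 1.35 and -1.51 (-2.86). Among the 10, the mitochondrial fission factor MTFP1 stood at -1.68 and 1.59 (3.28 from 2 h to 8 h), the metalloprotease ADAM12 at -1.09 and 1.94 (3.03), and the ribosome biogenesis factor RRP7A at -1.01 and 1.12 (2.13). With signals under 36.92 raised to it, EGR3 fell at least 1.49-fold at 8 h and MTFP1 at least 1.26-fold at 2 h, so these turns rest in part on dim signals. From 2 h to 8 h, the same bounds gave a fall of at least 53.7-fold for EGR3 and a rise of at least 3.81-fold for MTFP1. These 6 were named for the size of their change, after their values were seen.

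Outside the genes tested, 4283 bright probe sets carried no single gene name. At 8 h, 488 of them differed from 0 h, 265 up and 223 down, beside 110 at 2 h, 310 at 4 h and 497 at 6 h. No explanation was tested for these.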

How the results depend on the processing

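The alternatives were planned before the data were examined. The counts of changed genes stayed within 1.5 times the reported ones under quantile normalization, both other pseudocounts, no filter on dim probe sets, the robust prior and the replicate block, which gave 646, 1884, 2844 and 3041 genes at 2, 4, 6 and 8 h. The other settings moved counts as follows, and the cause was not tested unless given. Scaling to a common median gave 432 genes at 2 h and 4 from 6 h to 8 h. Without the variance trend there were 384 at 2 h, 576 from 2 h to 4 h, and 0 in limma from 4 h to 6 h and from 6 h to 8 h (1722 and 919 at an unadjusted p under 0.05). With only the 4 arrays compared there were 390 at 2 h, 512 from 2 h to 4 h, and 0 from 6 h to 8 h (1208 at an unadjusted p under 0.05), with fewer arrays behind the variance. The mean of all probe sets of a gene gave 744 from 2 h to 4 h, 91 from 4 h to 6 h and 3 from 6 h to 8 h, and a stricter filter on dim probe sets 28 from 6 h to 8 h, among fewer genes. Counting all probe sets, which counts some genes more than once, gave 2996 at 4 h, 4796 at 6 h, 4991 at 8 h, 8 from 6 h to 8 h, 4349 from 2 h to 8 h and 5644 by the F test. Requiring a 2-fold change, which removes smaller ones, left 416, 991, 1396 and 1485 at 2, 4, 6 and 8 h, 619 from 2 h to 4 h, 137 from 4 h to 6 h and 1303 from 2 h to 8 h.

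Leaving out each array in turn gave 341 to 887 genes at 2 h, 1068 to 2234 at 4 h, 1702 to 3154 at 6 h, 1888 to 3325 at 8 h, 374 to 1490 from 2 h to 4 h, 48 to 280 from 4 h to 6 h, 0 to 28 from 6 h to 8 h, 1737 to 2650 from 2 h to 8 h and 2630 to 3923 by the F test. The arrays that moved a count by more than 1.5 times are named beside it above, except for further ones from 6 h to 8 h: 9 genes without 0 h replicate 1 or 0 h replicate 2, and 10 without 4 h replicate 1, 4 h replicate 2 or 8 h replicate 2. The 0 in limma without 6 h replicate 1, 6 h replicate 2 or 8 h replicate 1 stood beside 792, 642 and 736 genes at an unadjusted p under 0.05.

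Of 124 list results against 0 h, 71 were called. With an estimated correlation 46 lost their call, under quantile normalization 6 lost it and 6 gained it, and by fry 2 lost it and 25 gained it, while no list reversed under any setting run. Leaving out 1 array lost calls of these lists: SRF and MRTF genes at 2 h (adjusted p 0.0734 without 2 h replicate 2), proteases at 2 h (0.139 and 0.0955 without 0 h replicate 1 and 2 h replicate 1), nuclear import and synthetases at 2 h (0.0576 without 2 h replicate 2), and CDK inhibitors at 4 h (0.0714 without 4 h replicate 2). G1 cyclins lost theirs at 4 h without any of 5 arrays (0.051 to 0.086) and at 8 h without 0 h replicate 2 or 8 h replicate 1 (0.0528 and 0.0794). At 8 h the same held for ribosomal proteins (4 arrays, 0.0535 to 0.165), DNA replication (0.269 without 8 h replicate 1) and collagens (4 arrays, up to 0.187 without 0 h replicate 2, with 3 falls in place of 8). Of 899 values for named genes, 753 were called: 37 lost the call under quantile normalization, 101 with a common median, 191 without the variance trend and 30 with the replicate block. Under the mean of probe sets 136 of 714 called values lost it and 3 changed sign without passing the threshold, counted as reversed: CCDC85B at 2 h (0.778), COX4I1 at 4 h (0.1309) and PFKP from 2 h to 4 h (-0.09274). The labels do not say whether equal replicate numbers mark a shared culture or day. The differences between replicates of 2 times correlated across genes with r from -0.131 to 0.257 (median -0.04). These values showed no consistent pairing but cannot exclude one, and the block was not read as a paired test. Signal over background limits dim genes most, as in the simulated data.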

Other observations

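Of the tests in this part, the array left out for the tRNA synthetases and both the array and the scaling test for the BMP-response genes had their limits set before the result was seen; the others were chosen afterwards.

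The interferon response list was called down from 4 h on, whereas the clock list was not called. In the interferon response list 1 of 16 rose, 6 fell and 9 did not pass at 4 h, 5 fell and 11 did not pass at 6 h, and 8 fell and 8 did not pass at 8 h (6, 5 and 9 fell when adjusted over the list alone; camera adjusted p 0.0108, 0.0142 and 0.000174; adjusted p = 0.157, 0.164 and 0.0824 with an estimated correlation). At 8 h IFIT1 fell by 2.51 on the log2 scale (SE 0.32, n = 2 arrays at each time) and IFIT3 fell by 1.39 (SE 0.29). Of 13 clock genes, PER2 rose 3.1-fold and CRY1, both repressors in the clock's feedback loop, 2.45-fold at 2 h, and 11 did not pass (3 rose when adjusted over the list alone; camera adjusted p 0.0537). At 8 h CRY1 was up, the nuclear receptor NR1D2 fell at least 4.91-fold, TEF fell by 2.27 (SE 0.66) and DBP fell by 1.18 (SE 0.38), with 9 not past (1 up and 5 down when adjusted over the list alone; camera adjusted p 0.534).

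The lists of Notch and Wnt response, p53 targets and liver X receptor and PPAR targets were not called in a comparison with 0 h. Of 12 Notch and Wnt genes, the Notch targets HES1 (12.7-fold), HES4 (6.06-fold) and HEY1 (2.52-fold) rose at 2 h and 9 did not pass, also when adjusted over the list alone (camera adjusted p 0.0893). The folds of HES1 and HES4 are uncertain, since their mean signals at 0 h were 49.7 and 55.15 with SDs of 42.4 and 46.9. At 6 h 1 of the 12 rose, 3 fell and 8 did not pass, with log2 changes of -2.24 for the ligand JAG1, -2.06 for the receptor FZD7 and -1.11 for WNT5A (camera adjusted p 0.339). From 4 h to 6 h that list was called down, with 3 genes down and 9 not past (4 down when adjusted over the list alone, camera adjusted p 0.00151, adjusted p = 0.142 with an estimated correlation). Of 15 p53 targets, GADD45A (5.74-fold) and the kinase PLK3 (4.31-fold) rose at 2 h (2 up and 4 down when adjusted over the list alone; camera adjusted p 0.871), while at 8 h 2 rose, 5 fell and 8 did not pass, with DDB2, a DNA damage sensor, at -2.81 (camera adjusted p 0.218). ANGPTL4, an inhibitor of lipoprotein lipase in the list of liver X receptor and PPAR targets, rose at least 4.45-fold at 2 h and 21-fold at 4 h. Its signal at 0 h had a mean of 27.85 and an SD of 30.3, so these folds are uncertain. At 8 h 1 of the 10 genes of that list rose, 4 fell and 5 did not pass (2 up and 4 down when adjusted over the list alone, camera adjusted p 0.259). CPT1A, which couples fatty acids to carnitine, stood at -1.31 and the cholesterol transporter ABCA1 at -1.22.

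Aminoacyl-tRNA synthetases split at 8 h: 10 of 11 genes known as targets of ATF4, the transcription factor of amino acid shortage, fell (mean log2 change -0.752, SD 0.276), whereas 4 of 6 others rose (mean 1.17, SD 0.563), among them RARS1 at 1.88 and FARSA at 1.58. The difference was -1.92 (two-sided exact permutation over genes p 8.08e-05, the smallest these permutations can give, 0.000108 adjusted over the 4 times; -1.89 and p 0.000323 with VARS1 among the targets), beside -1.45 at 6 h, -0.764 at 4 h and -0.0307 at 2 h (exact p 0.738). The tables argued against a single array as the cause, since at least 97.1% of the difference stayed without any 1 of the 4 arrays. A shift common to all genes of an array cancels in this difference, so scaling to a common median (100% kept) could not test the scaling. Under quantile normalization, which can shift genes by their brightness, 98.7% stayed, which argued only against a scaling that varies with brightness. Lower ATF4 activity after serum may account for the falls, as a hypothesis found and tested on the same data. ATF4 fell at 4 h (-1.27). The amino acid and ER stress list holds other targets of ATF4 beside ER stress genes such as HSP90B1 and DNAJB9. Its calls are therefore no measure of ATF4 targets alone. That list was called down at 2 h and 4 h (camera adjusted p 0.00475 and 0.00951, adjusted p = 0.164 and 0.188 with an estimated correlation). It was not called at 6 h (4 of 22 up, 9 down and 9 not past, camera adjusted p 0.0644) or 8 h (6 up, 8 down and 8 not past, 0.393). The synthetase genes are not independent replicates, and their grouping was made after their values were seen. What raised the other synthetases was not tested.

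Some BMP-response genes dipped at 4 h: ID1, ID2, ID3, ID4 and SMAD6 fell from 2 h to 4 h (log2 changes of -2.07, -1.29, -1.25, -2.3 and -2.01) and rose from 4 h to 8 h (1.48, 1.41, 1.68, 1.09 and 2.41), as did 55 of all 12998 genes tested and 14 of the 469 that rose at 2 h. The tables argued against the 4 h replicate 1 array as the cause, since without it 5 of 5 genes kept both steps past the threshold. Scaling stayed open for ID4: with a common median per array its second step was 0.99 (adjusted p 0.0526), so 4 of 5 kept both steps, while under quantile normalization 5 of 5 did. A second BMP signal is a candidate explanation, and BMP2 rose at least 5.89-fold at 4 h, but 5 of 12 measured BMP targets showed both steps, so a shared signal cannot be told apart from causes particular to these genes. SMAD7 fell from 2 h to 4 h (-2.56) without a called second rise (0.55, limma adjusted p 0.153). SMAD9 and ATOH8 rose from 4 h to 8 h (1.67 and 2.33) without a called first fall. Neither step required a rise from 0 h to 2 h, and SMAD6 lay below its 0 h level at 4 h. The mean signal of ID4 was as low at 6 h (171.1) as at 4 h (183.2).

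The 15 cytosolic ribosomal protein genes had a median log2 change of -0.304 at 2 h. Lists of genes outside these 15, matched on brightness, had medians from -0.325 to -0.174 (the central 95% of 10000 draws). The ribosomal list lay at the 10.1 percentile of them. Ribosomal protein genes that are not in the list were not kept out of these draws. Under quantile normalization its median was -0.0376 (adjusted p 0.426). The lower values may follow a trend of bright probe sets on these arrays and its scaling. Quantile normalization evens out the brightest signals between arrays, and the draws could hold other ribosomal protein genes. Neither test could therefore tell such a trend apart from a shared fall of ribosomal protein genes. No biological explanation was tested.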
